A study of Schmidtea mediterranea with 10 samples.

How the data were processed

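Asexual Schmidtea mediterranea of strain CIW-4, kept at 20 °C and starved for at least 2 weeks, were dissociated and fixed in ACME for about 60 minutes, per the labels' protocols. About 160 worms were divided between a control without probes, the agat label and the piwi-1 label. The control without probes is not analysed here. Cells were strained at 70 µm and sorted by flow cytometry into a positive and a negative gate of each label. Libraries were made by SMART-seq v4 amplification of polyadenylated RNA and Nextera XT, which carry no molecular identifiers, so PCR copies of a molecule count as separate reads.

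The authors deposited 1 table of counts per gene and 1 table of TPM values (length-scaled transcript levels), each with 36035 genes and 10 libraries. The submitters' processing notes name STAR 2.7.10b and RSEM 1.3.1. The deposited counts have the layout of STAR gene counts, and the TPM values come from the authors' other table. The genome build, annotation and strand setting are not given in the sources used here. The name column of the deposited TPM table repeats the ID in all 36035 rows, so 20 gene lists fixed by gene name could not be used. Columns were matched to samples through the column names in the labels. The columns of both libraries numbered 4 are named in another form than those of replicates 1 to 3. Columns of replicates 1 to 3 share a number that those of the libraries numbered 4 lack, and its meaning is not given. Whether replicates 1 to 3 came from the same sort, and those numbered 4 from another, is not given in the sources used here.

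The count table has 4 rows that name no gene (unmapped, multimapped, ambiguous and without feature). Together the 4 rows held 22.8% to 36.98% of the reads of a library and were left out of library sizes and tests. The ambiguous and without-feature rows held 0 reads in all 10 libraries. Whether reads were mapped to a genome or to transcripts is not given in the sources used here. Libraries held 35081410 to 51821158 assigned counts. At this depth the counting error of reads should be small beside the spread between replicates for genes of 10 CPM or more. The error from sampling molecules before amplification was not measured.

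agat-positive and agat-negative libraries (4 against 4) were compared with edgeR 4.0.16 in R 4.3.3, by a two-sided quasi-likelihood test on the deposited counts with TMM factors, filterByExpr and robust dispersion, without a replicate block, at a Benjamini-Hochberg adjusted p under 0.05. The filter left 22954 genes. The SE of a log2 fold change was taken from the estimate and its F statistic. CPM values are relative to all assigned counts of a library, without TMM factors unless stated. Exact permutation tests used all 70 assignments of the 8 libraries, on log2 of TMM-scaled CPM + 1 for genes and on log2 ratios of TPM for the agat proportions.

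The piwi-1 pair has 1 library per gate and no test. Ratios of CPM carry 95% exact binomial (Clopper-Pearson) intervals and CPM values exact Poisson intervals. The piwi-1-high and piwi-1-low sets are the 200 highest and 200 lowest log2 ratios of CPM + 1 among genes with a mean CPM of 10 or more. They were tested in the agat comparison with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. A list's median in the piwi-1 pair was placed among 10000 random lists matched over 20 expression bins.

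The comparisons, tests, other settings to try and the rule for named genes were fixed before the data were examined. The rule names the 4 probe targets and, where IDs have no names, the 2 IDs with the largest changes each way among called genes with a mean CPM of 10 or more. No called gene met it, and the 2 called genes were named after their values were seen. The agat-high and agat-low sets were planned from called genes of 10 CPM or more, and so were empty. After seeing the data they were redefined as the 200 largest changes each way among genes of that level whose groups did not overlap in TMM-scaled CPM. Overlap of groups was counted at first in library-size CPM, and then in TMM-scaled CPM to match the edgeR test. Set overlaps, library shares, positions of single libraries and counts of genes far from the other libraries were also added then.

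The other settings tried were other scaling factors, DESeq2 1.42.0, other filters, the replicate block, each library left out, both libraries numbered 4 left out, glmTreat against a log2 fold change of 1, limma-trend on log2(TPM + 1) and log2(TPM + 0.1), thinning to the smallest library, and limma-voom with sample quality weights. Over all genes the median log2 fold change was -0.06 with TMM, -0.17 with library size only and -0.23 in TPM, so fold changes on those scales are to be read against that shift. Scripts were tested on simulated counts with 200 changed genes. Libraries of 1 group differed by far more than the sampling noise of reads, with a chi-square per gene of 11.8 to 301. None therefore repeats the counts of another. The lowest value was between agat-positive replicates 2 and 3 (Spearman correlation 0.971), and the next lowest was 41.4, between agat-positive replicates 1 and 4. PCR copies count as separate reads, so this measure cannot tell whether libraries came from the same sort or RNA. Python 3.11.15, pandas 2.3.3 and scipy 1.17.1 were used for the other calculations.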

Results

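RNA was sequenced from sorted cells of whole, uninjured planarians of the species Schmidtea mediterranea, a flatworm that rebuilds missing body parts. Cells were dissociated and fixed in an acetic acid and methanol mixture (ACME) and labelled by hybridization chain reaction, which makes cells fluoresce where a chosen transcript is present. Probes for 3 agat genes, used as a pool, gave 4 agat-positive and 4 agat-negative libraries, which the labels call biological replicates. A piwi-1 probe gave 1 positive and 1 negative library. The 10 libraries held 35081410 to 51821158 counts assigned to genes. The share of unmapped reads was 34.51% in agat-negative replicate 4 and 29.67% in the piwi-1-positive library, and ran from 19.68% to 24.49% in the others. The files do not pair gene IDs with names, so the 4 probe targets are the genes with a name here.

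The agat comparison asks which transcripts set cells with agat transcripts apart from the rest of the worm. All 3 agat transcripts were more abundant in each of the 4 agat-positive libraries than in any of the 4 agat-negative libraries. The agat genes encode relatives of L-arginine:glycine amidinotransferase, the enzyme of the opening step of creatine synthesis, and mark late progenitors of the planarian epidermis. agat-1 (SMED30018353) had 932 ± 766 CPM (counts scaled to the library total) in agat-positive and 42.8 ± 35.4 CPM in agat-negative cells (SD, n = 4), a fitted 24.4-fold difference. agat-2 (SMED30009513) had 896 ± 745 against 41.6 ± 27.6 CPM, 23.96-fold. agat-3 (SMED30019154) had 408 ± 320 against 13.5 ± 12.3 CPM, 34.3-fold. piwi-1 (SMED30007406), a PIWI-family gene that marks neoblasts, the dividing stem cells of planarians, was 1.47-fold less abundant in agat-positive cells, at 316 ± 98.1 against 497 ± 78.5 CPM.

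The agat-positive libraries differed widely in these levels. agat-1 stood at 1627, 305, 234 and 1564 CPM in agat-positive replicates 1 to 4, and at 14.7, 33.6, 94.6 and 28.4 CPM in agat-negative replicates 1 to 4. With this spread none of the 4 probe targets passed in edgeR over the 22954 genes tested. The log2 fold changes were 4.61 (SE 0.96) for agat-1, 4.58 (SE 0.96) for agat-2, 5.10 (SE 1.15) for agat-3 and -0.55 (SE 0.21) for piwi-1, with edgeR adjusted p of 0.20, 0.20, 0.207 and 0.391. The edgeR p adjusted over the list alone were 0.00321, 0.00321, 0.00371 and 0.0227. The gate was set on the agat transcripts, so the agat values check the sort and are not independent evidence. The piwi-1 value equals its unadjusted p, since this adjustment leaves the largest p of a list unchanged. It is therefore no corrected result for piwi-1. In exact two-sided permutation tests each of the 4 genes gave p = 0.0286, the smallest p that 4 against 4 libraries allow. The DESeq2 Wald test called all 3 agat genes, with adjusted p from 8.4e-06 to 4.4e-05. Without agat-negative replicate 3 the log2 fold changes of agat-1 and agat-3 were 5.28 and 5.78. Related copies can share reads, so the split of counts between the 3 agat genes is uncertain.

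**Figure D1:**
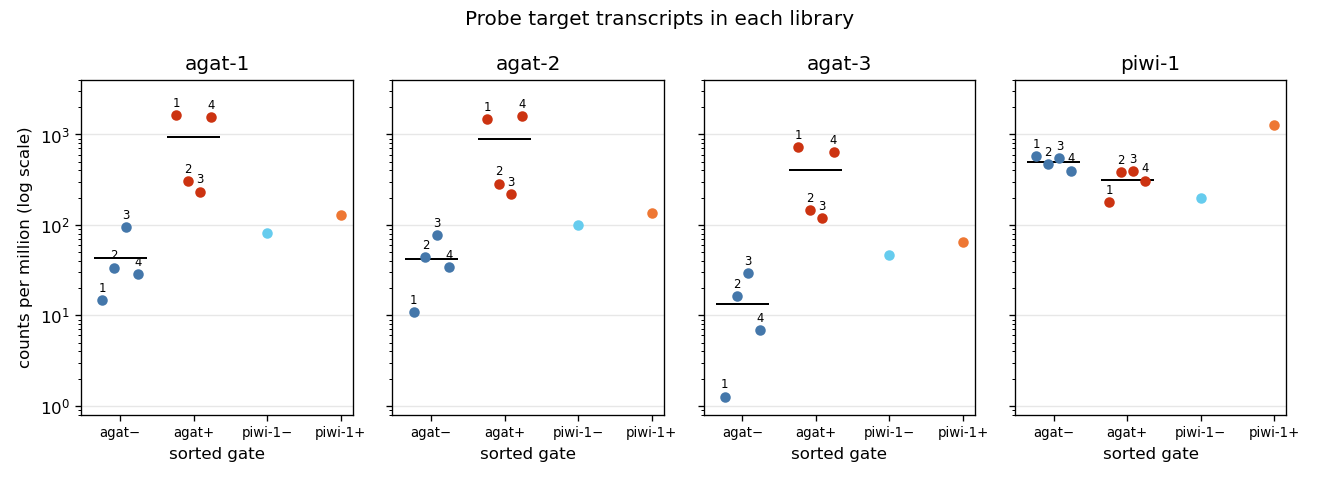
CPM (log scale) of agat-1, agat-2, agat-3 and piwi-1 in each sorted library, with 1 point per library, replicate numbers beside the points and black lines at the means of the groups of 4. All agat-positive libraries lie above all agat-negative libraries for the 3 agat genes, with agat-1 from 234 to 1627 CPM among the positive ones, and piwi-1 is highest in the piwi-1-positive library at 1267 CPM.

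The agat transcripts varied little in their proportions within the positive gate. In TPM, the length-scaled measure, agat-2 stood at 0.787 ± 0.048 of agat-1 in agat-positive and 0.825 ± 0.255 in agat-negative libraries (SD, n = 4; exact two-sided permutation p = 0.943). agat-3 stood at 0.446 ± 0.045 and 0.264 ± 0.152 of agat-1 (exact two-sided permutation p = 0.0857).

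Across all genes, 2 genes rose in agat-positive cells and 0 fell by edgeR. Their IDs are given because the count is small, and they were chosen after their values were seen. SMED30013218 rose from 1.51 ± 0.41 to 18.3 ± 6.19 CPM (SD, n = 4), with a log2 fold change of 3.72 (SE 0.34, edgeR adjusted p = 0.00801). SMED30029782 rose from 0.132 ± 0.107 to 2.68 ± 0.66 CPM, with a log2 fold change of 4.42 (SE 0.50, edgeR adjusted p = 0.0352). Both genes were higher in 4 of 4 agat-positive libraries than in any negative one. With the replicate block both genes lost their call (edgeR adjusted p = 0.117 for SMED30013218 and 0.217 for SMED30029782). SMED30013218 lost its call without agat-negative replicate 1 (edgeR adjusted p = 0.0621) or agat-positive replicate 4 (0.0626). SMED30029782 lost its call without agat-negative replicate 1, 3 or 4 or agat-positive replicate 1, 2 or 4 (edgeR adjusted p from 0.0567 to 0.197), and its log2 fold change was 5.02 without agat-negative replicate 2 and 2.24 in log2(TPM + 1). At an unadjusted p under 0.05, edgeR had 1208 genes higher and 1235 lower. Scaled by library size only, that split was 715 higher and 1930 lower.

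These counts of calls depended on the test and on single libraries. DESeq2, run without the edgeR filter and with a p for 34750 genes, called 403 genes higher and 78 lower. Of these, 357 and 73 had groups that did not overlap, which describes the same libraries and is not separate support. On simulated counts with 200 changed genes, DESeq2 called 57 unchanged genes and edgeR 8. There edgeR recovered 29.9% of 2-fold, 94% of 4-fold and 98.5% of 16-fold changes, where DESeq2 recovered 44.8%, 97% and 100%. All changed genes had a mean CPM of 10 or more. The recovery rates do not cover genes below that level, where both edgeR calls lay. The counts were drawn for the genes past edgeR's filter, with the dispersions that edgeR fitted. DESeq2 was run on those genes there, unlike its real run without the filter. The simulated genes varied independently of each other, and no simulated library stood apart from its group. These rates therefore need not hold for the real libraries, where many genes shared the spread between agat-positive libraries. Without agat-positive replicate 3, edgeR called 98 genes higher and 0 lower. It called 2 higher without agat-negative replicate 2, 1 higher without agat-positive replicate 1 or 2 or agat-negative replicate 3 or 4, and 0 without agat-positive replicate 4 or agat-negative replicate 1. In alternatives added after seeing the data, leaving out each pair of positive libraries gave 406 higher and 22 lower without replicates 2 and 3, and 0 to 2 higher without the other pairs. DESeq2 without agat-negative replicate 4 called 511 higher and 99 lower, with 360 and 51 of the same genes.

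The differences of large size were on the higher side. Among 8374 genes with a mean CPM of 10 or more, 655 were higher in all 4 agat-positive libraries than in all 4 negative ones and 320 were lower, in TMM-scaled CPM. Chance gives 1.43% each way on average, or 120 genes. Genes move together, so a single split of the libraries can lie far from that average, and this count was not made for other splits. This count was added after seeing the data and turns with the scaling, since library-size CPM gave 364 higher and 772 lower. At 4-fold or more, the TMM-scaled counts were 132 higher and 2 lower, and at 16-fold or more 58 higher and 0 lower.

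The 200 genes of the 655 with the largest fold changes, called the agat-high set, held 6.26 ± 4.49% of assigned counts in agat-positive and 0.760 ± 0.300% in agat-negative libraries (SD, n = 4). By library the share was 10.6%, 2.55%, 2.22% and 9.66% in agat-positive replicates 1 to 4, and 0.564%, 0.895%, 1.12% and 0.467% in agat-negative replicates 1 to 4. The set includes the 3 agat genes. The 200 genes of the 320 with the most negative fold changes, the agat-low set, held 1.44 ± 0.33% and 3.04 ± 1.51%, with 5.30% in agat-negative replicate 4. Both sets were picked on these libraries, so the shares describe them and are not a test.

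The piwi-1 pair compares neoblast-marked cells with the remaining cells, with 1 library per gate and so no replicate check. piwi-1 stood at 1267 CPM (95% exact Poisson interval 1255 to 1279) in the positive and 199.9 CPM (195 to 205) in the negative library, a ratio of 6.34 (95% exact interval 6.18 to 6.50). The agat transcripts were also somewhat more abundant in the piwi-1-positive library. agat-1 had 128 against 81.2 CPM, a ratio of 1.58 (1.51 to 1.66), agat-2 a ratio of 1.34 (1.28 to 1.40) and agat-3 a ratio of 1.42 (1.33 to 1.52). These agat levels lie below the 234 CPM of the lowest agat-positive library for agat-1. The direction held with TMM scaling and in TPM, but the size moved. The log2 ratios of 0.65, 0.42 and 0.50 became 0.40, 0.17 and 0.25 with TMM scaling and 0.88, 0.55 and 0.75 in TPM. SMED30013218 had 45 and 46 counts in the piwi-1-positive and piwi-1-negative libraries, and SMED30029782 had 7 and 11. Intervals cover counting error only.

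Among 8146 genes with a mean CPM of 10 or more in the piwi-1 pair, 1178 had a log2 ratio of 1 or more and 769 of -1 or less. The numbers were 283 at 2 or more, 56 at -2 or less, 20 at 4 or more and 11 at -4 or less, around a median of -0.05. The 200 highest ratios, which include piwi-1, ran from 2.29 to 7.76 and form the piwi-1-high set. The 200 lowest ran from -7.04 to -1.44 and form the piwi-1-low set.

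The genes of the piwi-1-high set were on balance lower in agat-positive than in agat-negative cells. Of the 200 genes, 157 had a log2 fold change below 0, with a median of -0.26. No member passed in edgeR over all genes (0 higher, 0 lower) or when adjusted over the list alone (0 and 0), and at an unadjusted p under 0.05 there were 45 lower and 0 higher. The set passed in limma's camera with a preset correlation (adjusted p = 3.8e-08, two-sided) but not with the correlation estimated from the data (limma adjusted p = 0.319 with an estimated correlation) or in limma's fry (adjusted p = 0.125). Its median log2(CPM + 1) per library was 3.48, 3.43, 3.27 and 2.82 in agat-negative replicates 1 to 4, and 2.86, 2.95, 3.00 and 2.79 in agat-positive replicates 1 to 4. agat-negative replicate 4 lay within the range of the positive libraries in this measure, but with TMM scaling it had 3.03, above the 2.87 to 2.99 of the positive libraries. Without agat-negative replicate 1 the median log2 fold change was -0.14, with 131 genes below 0.

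The piwi-1-low set showed no shift that passed. Of its 200 genes 122 were below 0, with a median of -0.13 and a limma camera adjusted p of 0.462, and 0.815 with an estimated correlation. No member passed in edgeR (0 higher, 0 lower, and 0 of each adjusted over the list alone), and at an unadjusted p under 0.05 there were 19 higher and 24 lower. Without agat-positive replicate 2 the limma camera adjusted p was 0.0494, and without agat-positive replicate 1 or 4 camera's direction relative to other genes turned (0.319 and 0.723). The median was -0.26 without agat-positive replicate 2, -0.23 without replicate 3, -0.04 without replicate 4 and -0.0028 without replicate 1, where 100 of the 200 genes were below 0, and -0.05 without agat-negative replicate 3.

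**Figure D2:**
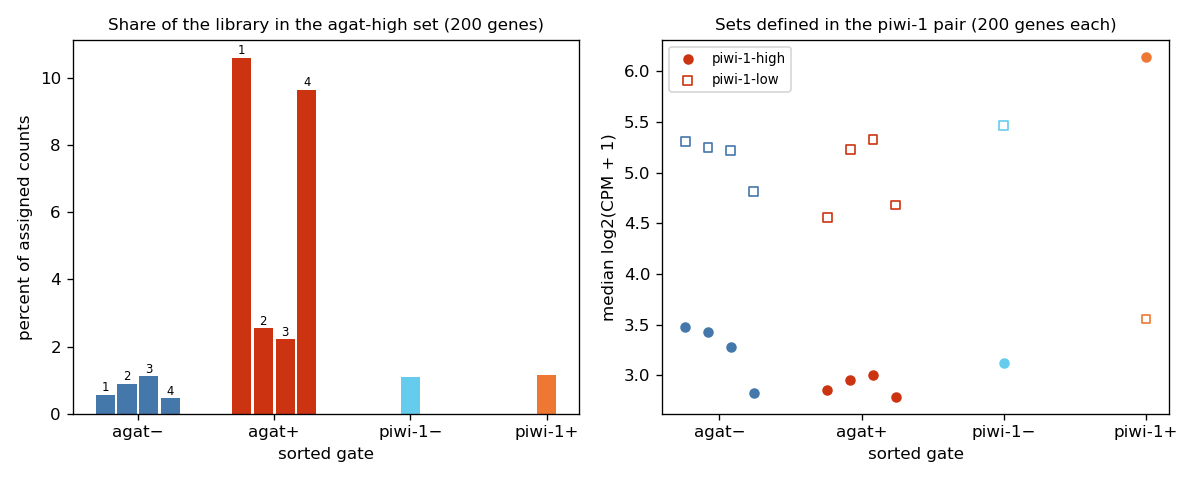
Left, percent of assigned counts in the 200 genes of the agat-high set, with 1 bar per library and replicate numbers above the bars. Right, median log2(CPM + 1) of the piwi-1-high set (filled circles) and the piwi-1-low set (open squares) per library, with agat replicates 1 to 4 from left to right; the agat-high set reaches 10.6% in agat-positive replicate 1, and the piwi-1-high set lies between 2.79 and 3.48 in the 8 agat libraries.

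In the reverse direction, the agat-high genes lay within the range of random lists in the piwi-1 pair. The 134 members expressed there had a median log2 ratio of -0.17, at percentile 11.6 of 10000 random lists matched on expression, of which 95% lay between -0.26 and 0.17. By size, 8 were at least 2-fold higher and 6 at least 2-fold lower in the piwi-1-positive library. The 166 agat-low members had a median of -0.11, at percentile 29.1, yet went both ways, with 65 at least 2-fold higher and 41 at least 2-fold lower. With TMM scaling these counts were 4 higher and 20 lower for agat-high, and 60 and 61 for agat-low.

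Overlaps were counted over the 7569 genes with a mean CPM of 10 or more in both comparisons, which hold 134 agat-high, 166 agat-low, 86 piwi-1-high and 193 piwi-1-low genes. The agat-low and piwi-1-high sets shared 16 genes, where independent lists would share 1.89 (two-sided Fisher's exact test, adjusted p = 1.4e-10 over 4 overlaps). agat-low and piwi-1-low shared 9 against 4.23 (exact, adjusted p = 0.0779), agat-high and piwi-1-high shared 0 against 1.52 (adjusted p = 0.544), and agat-high and piwi-1-low 2 against 3.42 (adjusted p = 0.778). Genes are not independent replicates, so these Fisher p-values can be too small. No library is shared between the comparisons. The overlaps were not recounted without agat-negative replicate 4, which held the largest share of counts in the agat-low set. Over the same genes, the agat log2 fold changes and the piwi-1 log2 ratios had a Spearman correlation of -0.056 and a Pearson correlation of -0.035 across genes.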

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

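The tests of explanations in this part were chosen after the result was seen. In 38 groups of 4 libraries, each tested for a single value far from the others, 2 values stood out, both in agat-negative replicate 4. Chance alone gives such a value in about 1 of 20 groups, so by number 2 of 38 is about what chance gives. The 38 hold related measures on the same agat libraries. The agat-low set, picked on these libraries, held 5.30% of the assigned counts of agat-negative replicate 4, against 2.16% to 2.37% in the other agat-negative libraries. In TMM-scaled CPM, 18.3% of its genes lay at least 2-fold from the median of the other negative libraries, against at most 2.21% for each of those.

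The genes that set agat-negative replicate 4 apart numbered 770 above and 764 below in TMM-scaled CPM, but 249 above and 1596 below in library-size CPM (22.0% of genes), so their balance depends on the scaling. Its larger share of unmapped reads alone does not account for the 18.3%, which was counted over assigned reads. Sampling noise from few starting molecules would fall with expression. The share was 20.3% at a mean CPM of 100 or more (other negative libraries 4.19% to 5.74%) and 18.8% at 10 to 20 (0.973% to 1.48%). It lay 14.6 and 17.3 percentage points above the highest of the others, which argues against such noise as the whole cause. Relative to the others, the excess was smaller at high expression. agat-negative replicate 4 also had the fewest genes with a count, 28497 against 30435 to 31213 in the other negative libraries. Such noise as a part of the cause stays open. The labels name the columns of both libraries numbered 4 in another form than those of replicates 1 to 3, and do not say whether they come from another sort. The deviations of both libraries numbered 4 correlated at -0.0203. All pairs of a positive and a negative library gave -0.042 to 0.046, so this measure alone does not decide on a common shift. In TMM-scaled CPM, 4.30% of genes in agat-positive replicate 4 lay at least 2-fold from the other positive libraries, which themselves had 3.64% to 6.29%. This argues against a common shift as large as that of agat-negative replicate 4. A smaller common shift, an effect on agat-negative replicate 4 alone and another makeup of its cells stay open, and no biological explanation was tested.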

How the results depend on the processing

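The 6 pairs of left-out positive libraries and DESeq2 without agat-negative replicate 4 were added after seeing the data. The 3 agat genes stayed higher and piwi-1 lower in agat-positive cells under all 29 alternatives, with a varying call. The count of higher genes, 2, was 403 with DESeq2 (78 lower), 1 with library size only, 1 with the 5 CPM filter, 1 with glmTreat, and 0 in the 3 TPM settings, with voom sample weights and without both libraries numbered 4. The labels do not say whether a replicate number ties a positive to a negative library. Same-number deviations correlated at 0.007, -0.027, -0.020 and -0.020, within the -0.042 to 0.046 of all such pairs. They show no shared deviation and cannot settle whether the sorts were paired. The replicate block gave 0 higher and 0 lower. The count ran from 0 to 98 with each library left out, and 0 fell in each. Without pairs of positive replicates it was 406 (22 lower) for 2 and 3, 1 for 1 and 2, 2 for 2 and 4, and 0 for 1 and 3, 1 and 4, and 3 and 4. DESeq2 without agat-negative replicate 4 gave 511 and 99. The cause was not tested. The agat genes passed in DESeq2 (log2 fold changes 4.62, 4.59 and 5.12), in DESeq2 without that library (4.54, 4.60 and 4.96), and agat-1 and agat-2 without positive replicates 2 and 3 (5.42 and 5.40). Their log2 fold changes were smaller with voom weights (3.26, 3.25 and 4.09) and smallest without positive replicates 1 and 4 (2.72, 2.66 and 3.38). SMED30013218 lost its call in 11 of 29 settings and SMED30029782 in 19, with 9 kept. The piwi-1-high set lost its call with an estimated correlation (limma adjusted p = 0.319) and in fry (0.125). The piwi-1-low set turned direction relative to other genes in camera without both libraries numbered 4 (limma adjusted p = 0.757) and without agat-positive replicate 1 (0.319) or 4 (0.723), and its adjusted p ran from 0.0494 to 0.990 with each library left out. The piwi-1 log2 ratio in its pair, 2.66, was 2.60 with 10 CPM added, 2.40 with TMM and 2.81 in TPM. With TMM the median of all genes there was -0.29, and the agat-high and agat-low medians were -0.42 and -0.36. The block changed no other call. Thinned to the smallest library, the same 2 genes were called.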

Other observations

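All explanations in this part were tested after the result was seen. For genes picked as much higher in agat-positive replicate 1, outside the probe targets, the other agat-positive libraries stood much as they did for the agat genes. Of genes with a mean CPM of 10 or more, 152 had at least 4 times as much TMM-scaled CPM in agat-positive replicate 1 as in every negative library. On a scale from 0 at the negative mean to 1 at agat-positive replicate 1, their median position was 0.155 in replicate 2 (quartiles 0.144 to 0.169), 0.124 in replicate 3 (0.112 to 0.138) and 0.833 in replicate 4 (0.768 to 0.906). agat-1 stood at 0.150, 0.109 and 0.929, agat-2 at 0.154, 0.113 and 1.05, and agat-3 at 0.169, 0.134 and 0.856. Positions were at first taken over genes called without agat-positive replicates 2 and 3, and redone on genes picked from replicate 1 so that no libraries were grouped by their outcome. The 2 called genes stood elsewhere, SMED30013218 at 0.339, 0.607 and 0.702 and SMED30029782 at 0.507, 0.728 and 0.622. A test that asks for little spread within a group favours such genes, so this contrast describes the values and was not tested.

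For the spread of the agat transcripts between agat-positive libraries, a full exchange of a positive and a negative library is argued against. The highest negative library had 94.6 CPM of agat-1 and the lowest positive one 234 CPM. These 2 values do not bear on a partial exchange. A candidate explanation is that replicates 2 and 3 held more cells without agat transcripts: agat-1 and the median of the other higher genes lay within 0.0960 of each other in replicates 2, 3 and 4, as a mixture would give, but lower transcript levels per cell would give the same. For the 95 genes at least 2-fold lower in replicate 1 than in every negative library, the median position in replicate 2 was 0.431 (0.205 to 0.536), above the 0.155 of the higher genes, but 0.250 (-0.041 to 0.402) for the 147 such genes without agat-negative replicate 4. In replicate 3 it was 0.411 (0.292 to 0.524) and 0.265 (0.020 to 0.397), against 0.124 and 0.119 for the higher genes, and in library-size CPM without agat-negative replicate 4 it was 0.296 (0.138 to 0.430) against 0.127, so the lower genes speak against a mixture alone in some settings and leave it open in others. piwi-1 stood at 0.347, 0.308 and 0.526 in replicates 2, 3 and 4, away from the higher genes in each. No biological explanation was tested.

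Chance could not be excluded for the number of edgeR calls or for the median changes of the piwi-1-high and piwi-1-low sets. Splits were not run for the DESeq2 calls or for the genes whose groups did not overlap. Of the 35 splits of the 8 agat libraries into 4 and 4, 2 gave 2 called genes or more, the real one included (highest other 2). For the size of the median change of the piwi-1-high set, 0.26 in the real split, it was 6 of 35, the real one included (highest other 0.324), and for the piwi-1-low set, 0.13 in the real split, 11 of 35, the real one included (highest other 0.250). In the first 2 principal components, which held 37% and 22.9% of the variance, agat-negative replicate 4 lay at -138.9 on the first, where the other 7 libraries ran from -29.6 to 76.2.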
